A study of Rattus norvegicus with 6 samples.

How the data were processed

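The series holds 6 Affymetrix expression arrays of primary rat hepatocytes, the parenchymal cells of the liver, kept in culture after isolation from male Sprague-Dawley rats. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. 3 arrays came from untreated cells (Control) and 3 from cells exposed to 50 µM trimethylamine N-oxide (TMAO) for 30 h. Groups and replicate numbers were taken from the sample titles. The labels call the samples biological repeats, and nothing in the sources used here says whether equal numbers in the 2 groups came from the same animal or isolation. The p-values of single genes therefore measure only the spread between these arrays.

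The values analysed were the log2 signals that the authors deposited in the series' value table, with 1 value per probe set and array. Background correction, normalization and probe summary behind these log2 values are not given in the sources used here. The submitters' processing notes name limma, with no version and no role. The medians of the 6 arrays lay between 5.53 and 5.61, and the deposited log2 values were used without another normalization. A further deposited table of signals has 6 columns numbered from 1 to 6, with no label that ties a number to a sample, so these 6 columns were not used here.

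The value table has 24871 probe sets, of which 1683 were controls and were left out. Of the other 23188 probe sets, 15049 had 1 gene symbol in the platform annotation, 0 had several and 8139 had none. All 15049 gene identifiers were found in the RefSeq gene table of the rat assembly GRCr8, and 0 symbols changed through it. A gene with more than 1 probe set, which held for 10 genes, was represented by the one with the highest mean over all 6 arrays, leaving 15037 genes. The 8139 probe sets without a symbol are unnamed here and were taken from a separate fit of all 23188 probe sets, with p-values adjusted over these. No coordinates are given, because the sources used here name no genome build for the probe sets. The number of arrays limits the precision of every value.

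TMAO was compared with Control by limma (version 3.58.1, in R 4.3.3). A linear model with the group as its only term was fitted to the log2 values of all 6 arrays with lmFit, and the spread was moderated with eBayes. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 15037 genes, and the threshold was an adjusted p of 0.05. A second, descriptive count took genes that differed at least 1.5-fold at an unadjusted p under 0.05. Differences are TMAO minus Control on the log2 scale, and their errors are standard errors (SE) of the fit. Every adjusted p of a gene comes from this limma fit.

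27 gene lists of pathways, of hepatocyte identity and of the other cell types of a liver preparation were fixed before the data were examined. They hold 648 entries, of which 585 were measured, and an entry that matched no named probe set was not analysed here. Each list was compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 27 lists. The p-values of this test rest on that assumed correlation and do not measure how far a whole list varies between arrays. Camera with an estimated correlation was run beside it. So was fry, which asks whether a list's genes move one way on balance and compares them with no other genes. Within each list, genes were also adjusted over the list alone.

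The genes named were chosen by a rule fixed before the data were examined. It took the genes past the adjusted threshold with no overlap between the groups and a mean signal at or above the 25th percentile, filled up to 10 per direction by the smallest unadjusted p among genes that differed at least 1.5-fold without overlap. Only 8 genes with lower signal under TMAO met it. It also took up to 4 members of each list by smallest unadjusted p, of which 4 are given for each list past the threshold and 1 for each other list, and Eif2ak3, Atf4, Ddit3, Foxo1, G6pc1 and Pck1. Wars1, Sars1, Sars2 and Aars2 were added after their values were seen, from 6 gene families picked by symbol after the results were seen and tested in the same way. 16 of the named genes had a mean signal less than 1 log2 unit above the median of the negative controls, a limit set after the results were seen. They were G6pc1, Pck1, Cdh5, Postn, Anxa13 and Zfp763 in both groups, Hspa4l, Slc7a11, Soat2 and Nr4a1 in Control, and Lck, Gmnn, Mcm3, Pfkfb1, Socs3 and Cd163 under TMAO. With signals this close to background, the sizes of their differences are uncertain.

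The procedure was tested on simulated data with the real means and spreads, in 20 runs with 200 changed genes each among the 15037. It recovered 52.1% of genes changed 1.5-fold, 98.6% of those changed 2-fold and 100% of those changed 3-fold, and 6.13% of its calls were false. These rates hold for 200 changed genes, and with fewer changed genes the adjusted threshold is harder to pass. In the real data only 4 genes passed, and Hspa4l (3.61-fold) and Ddit3 (3.39-fold) did not. The rates therefore do not carry over to the real comparison. A list of genes shifted by 0.3 on the log2 scale was called in 20 of 20 runs with the preset correlation and in 16 with an estimated one. With the preset one, 0 of 520 other lists were called. The simulated noise was independent between genes, so these runs do not show how often lists of correlated genes would be called falsely.

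Alternatives fixed before the data were examined were quantile normalization, median centring, a filter on dim genes, the mean of a gene's probe sets, every probe set tested on its own, eBayes with trend and robust estimation, array weights, the replicate number as a block, and each of the 6 arrays left out in turn. Their effects are given in the closing section.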

Results

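Gene expression was measured in cultured primary rat hepatocytes that were left untreated (Control, n = 3) or exposed to 50 µM TMAO for 30 h (n = 3). TMAO is a metabolite made in the liver from trimethylamine, which gut microbes release from choline and related nutrients. The comparison asks which hepatocyte transcripts differ after exposure to TMAO. The 6 arrays had median log2 signals of 5.53 to 5.61 over all 24871 probe sets, controls included. Correlations between arrays across the 15037 genes, which are not independent replicates, ran from 0.985 to 0.993. TMAO replicate 3 stood apart from the other 5 arrays on the first principal component, which held 30.8% of the variance. That array also had the highest mean signals of the labelling and hybridisation controls (7.91 and 10.09, against at most 7.54 and 9.91 on the others). Control replicate 3 had the most extreme value on the second component, which held 25.4%.

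Hepatocytes exposed to TMAO had higher levels of genes of the unfolded protein response, the programme that cells switch on when misfolded proteins build up in the endoplasmic reticulum (ER). All 31 measured genes of its PERK-ATF4 arm and 27 of 28 of its other arms and ER chaperones had higher means, and both lists passed the list test with the preset correlation (adjusted p of 2.7e-38 and 2.6e-28) but not with an estimated one (adjusted p = 0.215 for each). Herpud1, which acts in ER-associated degradation, rose 3.49-fold, and Hspa5, the abundant ER chaperone also called BiP, rose 2.03-fold. Vldlr, a lipoprotein receptor of the fixed PERK-ATF4 list, rose 3.14-fold, and Tgfbi, a secreted matrix protein, rose 2.09-fold. These 4 genes were the only ones of 15037 past the adjusted threshold, each with an adjusted p of 0.0373 and with all 3 TMAO arrays above all 3 Control arrays. Of 24 genes of DNA replication and cell division 23 had lower means, with an adjusted p of 1.0e-09 for the list and an adjusted p = 0.215 with an estimated correlation, and 0 single genes passed in the lower direction.

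Herpud1 (probe set TC1900001004.rn.2) had a log2 signal of 7.91 ± 0.18 in Control and 9.71 ± 0.38 under TMAO (mean ± SD, n = 3), a difference of 1.80 ± 0.19 (SE). Hspa5 (TC0300000287.rn.2) had 11.02 ± 0.12 in Control and 12.04 ± 0.09 under TMAO, a difference of 1.02 ± 0.12. For Vldlr (TC0100003418.rn.2) the difference was 1.65 ± 0.19, from 5.67 ± 0.25 in Control. For Tgfbi (TC1700001284.rn.2) it was 1.06 ± 0.11, from 8.49 ± 0.07 in Control. The next genes by the naming rule had an adjusted p of 0.102 and no overlap between the groups. Among them, Ddit3, the stress transcription factor CHOP, differed by 1.76 ± 0.26, Slc7a5, a carrier of large neutral amino acids, by 1.32 ± 0.19, and Inhbe, a subunit of activin secreted by the liver, by 0.93 ± 0.13. Elmod1 differed by 0.78 ± 0.12. The 8 genes that met the rule in the lower direction had adjusted p of 0.278 to 0.877. Beside Gmnn, Mcm3 and Fcgr2a, given with the cell cycle, they were Lck (-0.62 ± 0.12), Septin8 (-0.60 ± 0.19), Nmur1 (-0.59 ± 0.21), Zfp763 (-0.67 ± 0.24) and Ifitm1 (-0.86 ± 0.32). The last 3 came to -0.34 without TMAO replicate 3, -0.35 without TMAO replicate 1 and -0.43 without Control replicate 2.

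At an unadjusted p under 0.05, 825 genes differed, 452 higher and 373 lower, where 751.8 were expected by chance. Of these, 99 differed at least 1.5-fold, 87 higher and 12 lower, and 25 of the 99 belonged to the 59 genes of the 2 unfolded protein response lists. All 24 genes that differed at least 2-fold were higher under TMAO. The groups did not overlap for 10.8% of genes, where chance gives 10%. Leaving out 1 array changed the count of 4, to 2 (Vldlr and the chemokine gene Ccl3) without TMAO replicate 1 and to 0 without each of the other 5, and the count of 99 became 166 without TMAO replicate 2. The 12 lower genes became 35, 28 and 34 without Control replicates 1, 2 and 3, and 30, 32 and 25 without TMAO replicates 1, 2 and 3. Past 2-fold, 3 genes were lower without Control replicate 1 and 2 without Control replicate 3, and the 24 higher ones became 12 without TMAO replicate 3. When every probe set was tested on its own 0 genes passed, with a lowest adjusted p of 0.0549. With the replicate number as a block 0 passed too, with a lowest adjusted p of 0.207. With trend and robust estimation of the spread 30 passed, all higher and the 4 among them.

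**Figure D1:**
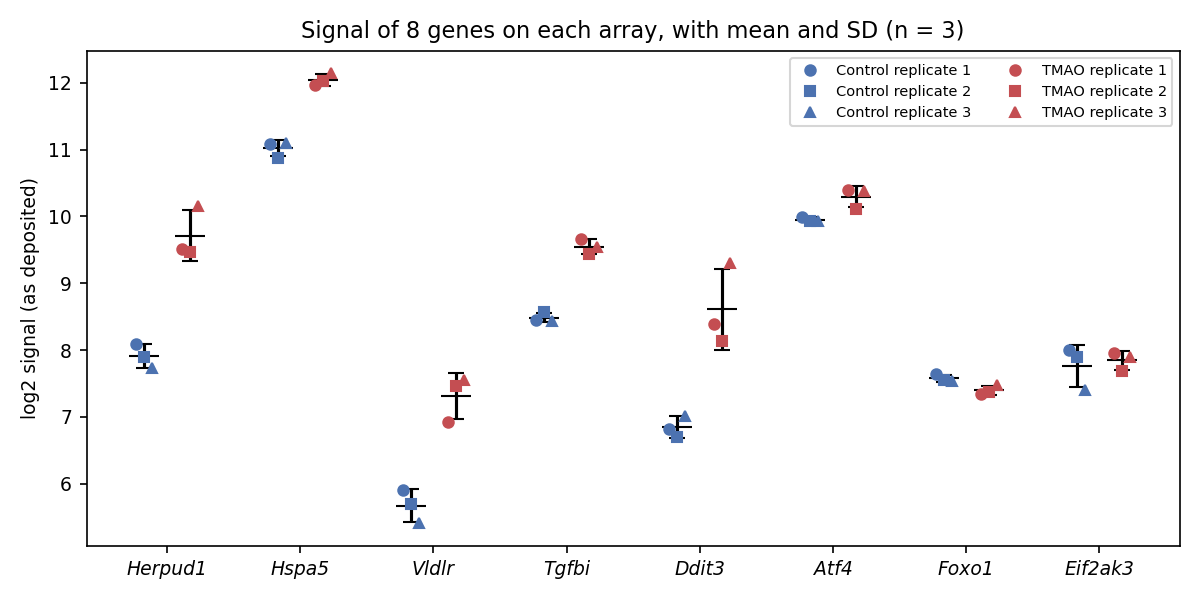
Log2 signal, as deposited, of 8 genes (horizontal axis) on each array, with Control in blue and TMAO in red, a marker shape per replicate number, and the mean and SD of each group (n = 3) in black. Herpud1, Hspa5, Vldlr and Tgfbi are separated by group, with differences of 1.80, 1.02, 1.65 and 1.06, while Eif2ak3 overlaps.

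The PERK-ATF4 arm of the unfolded protein response covers the targets of the translation-regulated transcription factor ATF4, many of which make or import amino acids. All 31 measured members of this list had a higher mean under TMAO, with a median difference of 0.59, or 1.5-fold. Camera with the preset correlation gave the list an adjusted p of 2.7e-38, and it had an adjusted p = 0.215 with an estimated correlation. 24 members passed when adjusted over the list alone, and 1 of them, Vldlr, when adjusted over all genes. Ddit3 differed 3.39-fold. Cth, which makes cysteine from cystathionine, differed by 1.41 ± 0.21, and Slc7a11, which imports cystine, by 1.71 ± 0.30. Atf4 itself differed by 0.34 ± 0.12, with an adjusted p of 0.856 over all genes and 0.0248 over the list alone. Eif2ak3, which encodes the kinase PERK, had a difference of 0.08 ± 0.17 and an adjusted p of 0.997. The sign of the Eif2ak3 difference turned without Control replicate 3, to -0.10, and with array weights, to -0.02.

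The ATF6 and IRE1 arms and ER chaperones, which expand the folding capacity of the ER, moved the same way. Of 28 measured members 27 were higher under TMAO, with a median difference of 0.42, or 1.34-fold. The list had an adjusted p of 2.6e-28 by camera and an adjusted p = 0.215 with an estimated correlation. 18 members passed when adjusted over the list alone, and 2, Herpud1 and Hspa5, when adjusted over all genes. Pdia4, a protein disulfide isomerase, differed by 1.10 ± 0.15, and Hyou1, an ER chaperone of the heat shock protein family, by 1.06 ± 0.15. TMAO replicate 3, the array that stood apart, had the highest level of both lists. Set against the mean of all 6 arrays, the PERK-ATF4 members averaged 0.35, 0.13 and 0.63 on TMAO replicates 1, 2 and 3, and -0.34, -0.44 and -0.33 on the Control arrays. Without TMAO replicate 3 the medians of the lists were 0.55 and 0.36.

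The cell cycle and proliferation list fell. Of 24 measured members 23 were lower under TMAO, with a median difference of -0.26, an adjusted p of 1.0e-09 by camera and an adjusted p = 0.215 with an estimated correlation. 2 members, Mcm3 and Mcm2, which are subunits of the replicative helicase, passed when adjusted over the list alone, and 0 when adjusted over all genes. Mcm3 differed by -0.71 ± 0.17 and Mcm2 by -0.46 ± 0.12, each with an adjusted p of 0.0394 over the list alone. Mcm6, of the same helicase, had a difference of -0.53 ± 0.15, and Ccnb1, the mitotic cyclin, one of -0.40 ± 0.13. Gmnn, an inhibitor of replication licensing outside the list, had the lowest p of the cell cycle genes named, with a difference of -0.76 ± 0.16 and an adjusted p of 0.367. Macrophage markers were also lower on balance, with a median of -0.09 over 19 markers and an adjusted p of 0.0963. It was 0.963 without Control replicate 2. The list passed without TMAO replicate 2 (0.0179), without Control replicate 3 (0.0246) and with array weights (0.0369). Among the markers Cd163, a scavenger receptor, had a difference of -0.39 ± 0.13, and Fcgr2a, an Fc receptor of macrophages outside the list, one of -0.63 ± 0.18.

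**Figure D2:**
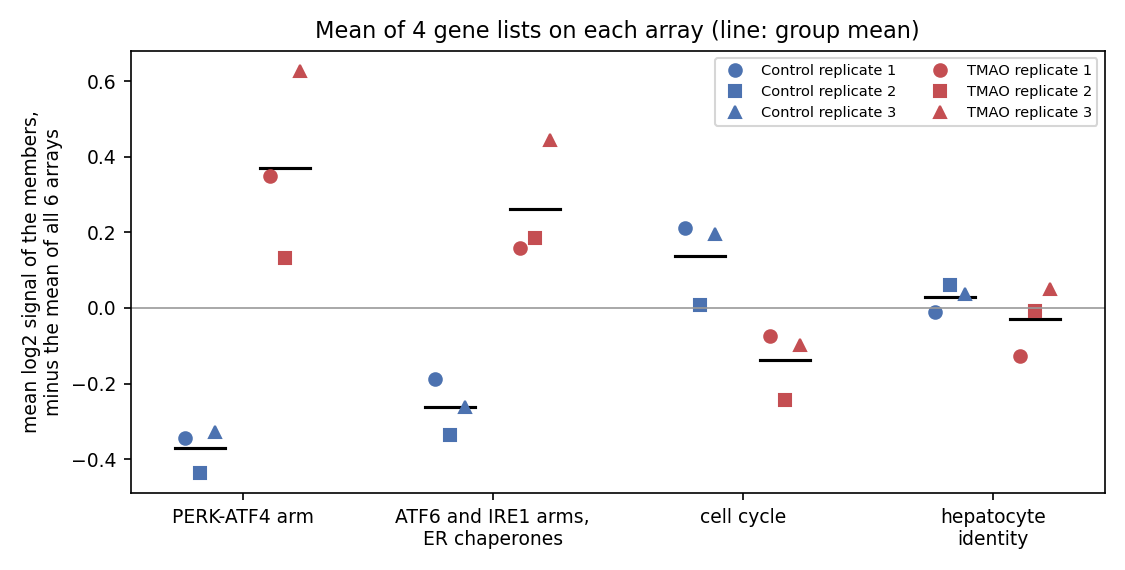
Mean log2 signal of the members of 4 gene lists on each array, minus the mean over all 6 arrays (vertical axis), with Control in blue, TMAO in red, a marker shape per replicate number and a line at each group mean. On the PERK-ATF4 list the Control arrays lie between -0.44 and -0.33 and the TMAO arrays between 0.13 and 0.63, and on the cell cycle list the 3 TMAO arrays lie below the 3 Control arrays.

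4 further lists passed with the preset correlation by smaller margins. Cholesterol synthesis and uptake genes were higher, with 13 of 20 members positive, a median of 0.18, an adjusted p of 0.0244 and an adjusted p = 0.503 with an estimated correlation. 0 of the 20 passed over the list alone or over all genes. Insig1, which retains the sterol sensor in the ER, differed by 0.73 ± 0.23, Mvd by 0.34 ± 0.13 and Fdps by 0.29 ± 0.12, the latter both enzymes of the mevalonate pathway, and Sqle, a later enzyme of the same synthesis, by 0.26 ± 0.14. Insig1 came to 0.45 without TMAO replicate 3, and Sqle to 0.14 without Control replicate 3. Cholesterol efflux and lipoprotein genes were lower, with 18 of 23 negative, a median of -0.10, an adjusted p of 0.0468 and an adjusted p = 0.340 with an estimated correlation. Over the list alone 1 gene was higher and 1 was lower, and 0 passed over all genes. The higher one was Soat2, which esterifies cholesterol (1.04 ± 0.26), and the lower one Apoc2, the activator of lipoprotein lipase (-0.52 ± 0.14). Apoc3, an inhibitor of the same lipase, had -0.44 ± 0.16, and Apoc1 had -0.29 ± 0.17. Soat2 came to 0.69 without TMAO replicate 3, and Apoc3 and Apoc1 to -0.28 and -0.13 without Control replicate 3. Without TMAO replicate 1, Control replicate 2, Control replicate 3 or TMAO replicate 3, both cholesterol calls were lost, with adjusted p of 0.140, 0.0864, 0.106 and 0.0786 for synthesis and 0.140, 0.0503, 0.124 and 0.102 for efflux. The efflux call was also lost without TMAO replicate 2, with an adjusted p of 0.114, and with array weights (0.0687), and the synthesis call with the filter on dim genes (0.108). With 1 array left out the medians ran from 0.13 to 0.20 for synthesis and from -0.16 to -0.07 for efflux, the latter without TMAO replicates 2 and 3.

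Acute-phase proteins, which the liver secretes in inflammation, were lower, with 17 of 21 negative and a median of -0.14. Their adjusted p was 0.00566 by camera, and they had an adjusted p = 0.602 with an estimated correlation. 0 members passed over the list alone or over all genes. Socs3, a feedback inhibitor of cytokine signalling, had a difference of -0.44 ± 0.12, Fga, a chain of fibrinogen, one of -0.32 ± 0.13, Crp one of -0.32 ± 0.14 and Apcs, a pentraxin, one of -0.30 ± 0.12. Fga came to -0.20 without Control replicate 3, and Crp to -0.20 without TMAO replicate 1. With 1 array left out their median ran from -0.26 without Control replicate 1 to -0.06 without TMAO replicate 1. Immediate early genes were higher, with 17 of 19 positive, a median of 0.07, an adjusted p of 0.0376 and an adjusted p = 0.503 with an estimated correlation. 0 of them passed over the list alone or over all genes, and Nr4a1, a nuclear receptor, differed by 0.46 ± 0.15. Fosl1 had 0.55 ± 0.25, Myc 0.44 ± 0.22 and Klf4 0.59 ± 0.31, and these 3 came to 0.32, 0.18 and 0.21 without TMAO replicate 3. Without TMAO replicate 1, Control replicate 2 or Control replicate 3 both calls were lost, with adjusted p of 0.385, 0.0503 and 0.124 for acute-phase proteins and 0.2195, 0.0503 and 0.306 for immediate early genes. The immediate early call was also lost without TMAO replicate 3, with an adjusted p of 0.0755, with quantile normalization (0.0778), with the filter on dim genes (0.126) and with array weights (0.120). Its median ran from 0.02 without Control replicate 3 to 0.13 without TMAO replicate 3.

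Gluconeogenesis and FoxO1 targets did not pass, with 14 of 24 members positive, a median of 0.05, whose sign turned without Control replicate 1, and an adjusted p of 0.516. Foxo1, a transcription factor of the fasting response, had a difference of -0.18 ± 0.11 and an adjusted p of 0.958. G6pc1 and Pck1, which catalyse committed steps of glucose production, had signals near or below the negative controls in both groups (means of 4.28 and 4.13, and of 3.78 and 3.66), so their differences (-0.15 ± 0.12 and -0.12 ± 0.14) do not measure their levels. Igfbp1, a secreted binding protein repressed by insulin, had 1.59 ± 0.43, with an adjusted p of 0.619, and came to 1.03 without TMAO replicate 3. Genes that handle methylamines, choline and one-carbon units did not pass either, with a median of 0.01 over 21 members, whose sign turned without Control replicate 1 or TMAO replicate 1 (-0.01 each), and an adjusted p of 0.980. Mat1a, which makes S-adenosylmethionine in the liver, had the lowest p of them, with a difference of 0.58 ± 0.16 and an adjusted p of 0.703.

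Hepatocyte identity genes had a median of -0.06 over 24 members and an adjusted p of 0.362, and the member of lowest p was Tdo2, a tryptophan-degrading enzyme, with -0.51 ± 0.16. Markers of other liver cells had medians of -0.03 for endothelial cells (17 members, adjusted p 0.577), -0.02 for stellate cells and fibroblasts (22 members, adjusted p 0.728) and 0.06 for cholangiocytes and progenitors (12 members, adjusted p 0.728). Without TMAO replicate 1 the sign of the hepatocyte median (0.0037) and of the cholangiocyte median (-0.01) turned, and without Control replicate 2 or TMAO replicate 3 that of the stellate median (0.0065 and 0.05). The endothelial median came to -0.11 without Control replicate 1, and the cholangiocyte median to 0.15 without TMAO replicate 3. Only 6, 11 and 8 of these markers lay at least 1 log2 unit above the median of the negative controls. 0 members of these 4 lists passed, over all genes or over the list alone. The endothelial cadherin Cdh5, with the lowest p of the endothelial markers, had means of 4.26 and 3.70, near or below the negative controls, so its difference (-0.57 ± 0.24) does not measure its level. In all, 7 of 27 lists passed with the preset correlation, 4 higher and 3 lower, and 4 passed without TMAO replicate 1 and 3 without Control replicate 2. 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and 0 passed by fry, where the lowest adjusted p was 0.0710 and 4 had an unadjusted p under 0.05.

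**Figure D3:**
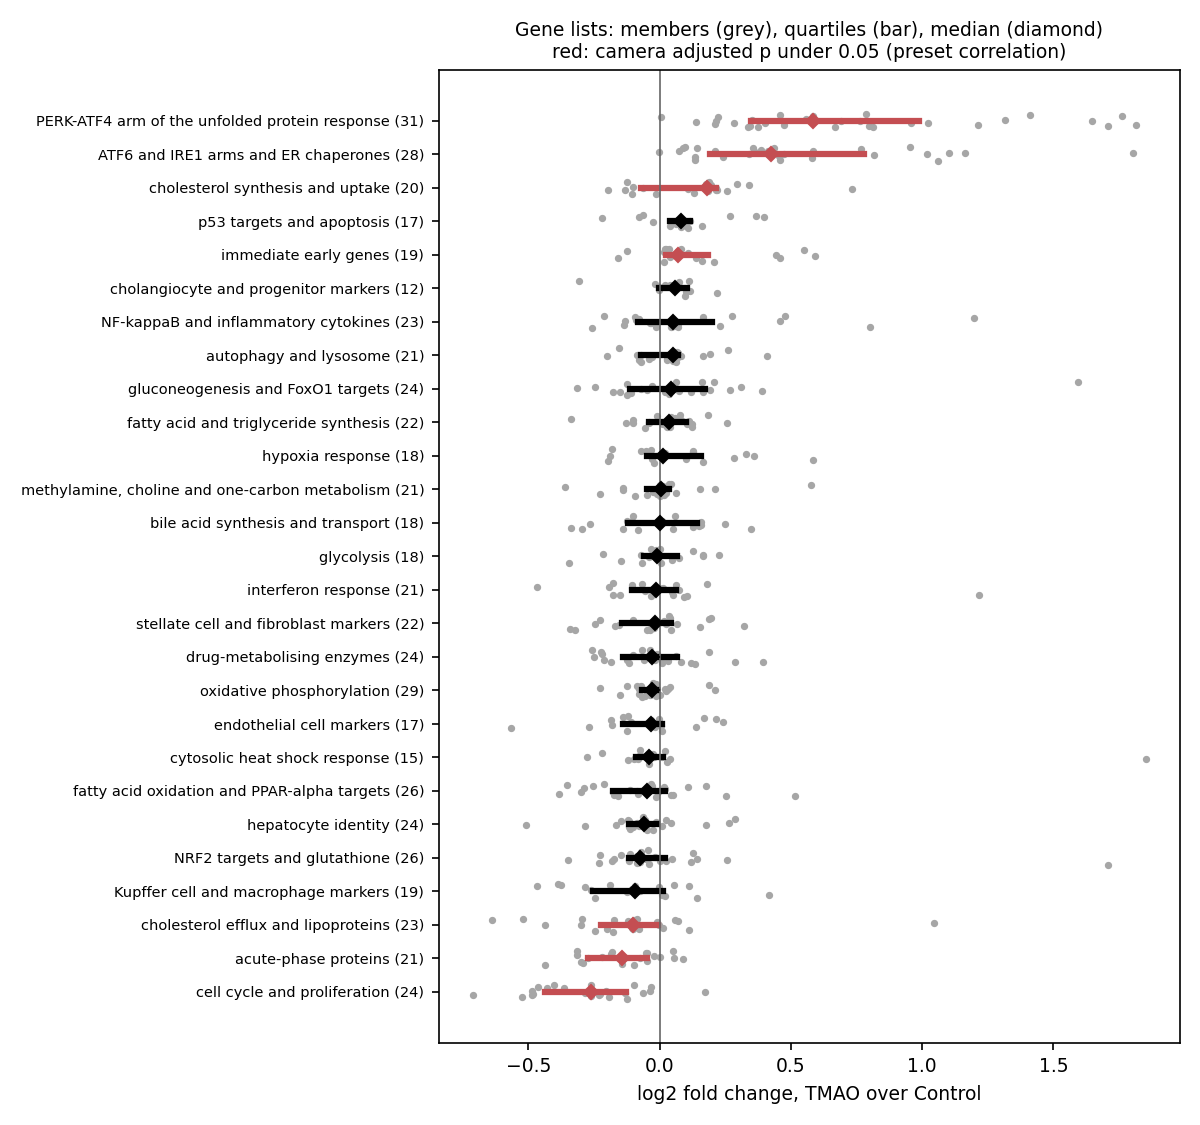
Log2 difference, TMAO minus Control (horizontal axis), of the measured members of each of the 27 lists (grey points, number in brackets), with the quartiles as a bar and the median as a diamond, in red where the adjusted p of camera with the preset correlation is under 0.05. The lists at the top are the PERK-ATF4 list (median 0.59) and the ER chaperone list (median 0.42), and the list at the bottom is the cell cycle list (median -0.26).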

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

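Every alternative in this part was fixed before the data were examined. The 4 genes past the adjusted threshold were the same 4 with quantile normalization, median centring and the mean of a gene's probe sets. There were 9 among genes at or above the median signal (7519 genes tested), 7 with array weights and 30 with trend and robust estimation, the 4 among them each time and all higher, and 0 when every probe set was tested. With the replicate number as a block 0 passed. The deviations of same-numbered arrays correlated by 0.13, 0.10 and -0.01. Numbers 1 and 2 correlated best with their own number (others up to -0.01 and 0.03) but number 3 did not. Some lists tracked the number in both groups. Against the mean of all arrays, NRF2 genes averaged -0.05, -0.09 and 0.13 on Control replicates 1, 2 and 3. On the TMAO replicates they averaged -0.04, -0.08 and 0.13. Drug-metabolising enzymes had -0.06, -0.06 and 0.16, and -0.06, -0.07 and 0.10. Others did not, such as p53 targets (-0.14 and 0.07 on number 3) and stellate markers (0.02 and -0.21). These hints go both ways. A shared source per number stays open, and leaving out an array would then break a pair. Leaving out 1 array left 0 to 2 genes, 84 to 166 genes past 1.5-fold, against 99, and 3 to 9 lists, against 7. Past 1.5-fold, array weights gave 73 higher and 26 lower, against 87 and 12. 0 lists passed with an estimated correlation and 0 by fry. In the 14 alternatives with the preset correlation the PERK-ATF4, ER chaperone and cell cycle lists passed each time, with medians of 0.52 to 0.69, 0.36 to 0.47 and -0.33 to -0.21. Of 914 values of 67 named genes, 862 kept direction and side of the threshold, 19 passed newly, 31 no longer passed and 2 reversed, both of Eif2ak3 (0.08), at -0.022 with array weights and -0.10 without Control replicate 3, from a range of -0.10 to 0.20 over the arrays left out. The cause was not tested. The other deposited table, detection calls and a pseudocount were not run, since its columns name no samples, no detection calls were used and the values are already log2. The number of arrays limits the precision, and dim probe sets have signals near the negative controls, whose medians were 3.87 to 4.03.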

Other observations

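The tests of gene families, of TMAO replicate 3 as the only source of the stress rise, of hepatocyte share on that array, and of macrophages and other cell types behind the cell cycle fall, with the margins they use, were chosen only after the results were seen.

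The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for protein synthesis, were higher as a family. All 16 measured genes picked for it, by a symbol ending in ars1, had a higher mean under TMAO, with a median of 0.41. Synthetase genes with other symbols were not included. The family had an adjusted p of 1.1e-14 by camera over 6 families and an adjusted p = 0.0589 with an estimated correlation. All 6 families were picked after the results were seen, so their p-values only describe them and are no separate evidence. 5 of the 16 also belong to the PERK-ATF4 list, and the family was not tested without them. Without TMAO replicate 3, 14 of 16 were higher (median 0.33). Wars1 differed by 0.78 ± 0.15 and Sars1 by 0.69 ± 0.14, with adjusted p of 0.251 and 0.278. The mitochondrial synthetases, picked by a symbol ending in ars2, had 6 of 13 members higher and a median of -0.0016 (adjusted p 0.871). Its sign turned without TMAO replicate 1 (0.0026), Control replicate 2 (0.01) or TMAO replicate 2 (0.01), and it came to -0.08 without TMAO replicate 3. Among them Sars2 had -0.17 ± 0.13 and Aars2 0.18 ± 0.17, which came to -0.05 without Control replicate 3 and 0.0055 without Control replicate 2. Slc7 amino acid transporters had 11 of 14 members higher, a median of 0.20, an adjusted p of 1.3e-04 and an adjusted p = 0.0589 with an estimated correlation. At an unadjusted p under 0.05, 3 members were higher and 1 was lower (-0.57). 2 of the 14, Slc7a5 and Slc7a11, also belong to the PERK-ATF4 list, and this family was not tested without them either. With the filter on dim genes only 3 of the 14 remained, with a median of 0.63. The 5 measured Mcm helicase subunits, all of them members of the cell cycle list and picked after its values were seen, were all lower, with a median of -0.46, which restates part of that list's fall. Without Control replicate 1 or TMAO replicate 2, 4 of the 5 were lower, and the 3 that the filter on dim genes kept had a median of -0.27. Proteasome subunits (37, median -0.03) and ribosomal proteins (69, median -0.00061) had adjusted p of 0.379 and 0.871. The sign of the ribosomal median turned without TMAO replicate 1 (0.0096), TMAO replicate 2 (0.02) or Control replicate 3 (0.01), and the proteasome median ran from -0.07 without TMAO replicate 3 to -0.0021 without TMAO replicate 2.

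In several stress and metabolic lists that did not pass, single members stood out. Hspa4l, a cytosolic chaperone of the Hsp110 family, had a difference of 1.85 ± 0.31 from a Control mean of 4.29, near the negative controls, which leaves its size uncertain, with an adjusted p of 0.185 over all genes and 0.00286 over the list alone, while the heat shock list had a median of -0.04 and a mean of 0.06 (adjusted p 0.678), the median coming to -0.08 without TMAO replicate 3, -0.07 without Control replicate 2 and -0.02 without TMAO replicate 2. The NRF2 and glutathione list had a median of -0.07 and a mean of 0.01 (adjusted p 0.516), and its 1 member past the threshold over the list alone was Slc7a11, which the PERK-ATF4 list also holds. Over their lists alone Ccl3, a chemokine (1.20 ± 0.26), Vegfa, an angiogenic growth factor (0.59 ± 0.14), and Acot1, an acyl-CoA thioesterase (0.51 ± 0.12), also passed. Their lists had medians of 0.05 for NF-kappaB and cytokines (adjusted p 0.191), 0.01 for hypoxia (0.262) and -0.05 for fatty acid oxidation and PPAR-alpha targets (0.3). The members of lowest p in the remaining lists, none past the threshold, were Tp53inp1 (0.37 ± 0.15, p53 targets), Atg3 (0.41 ± 0.14, autophagy), Mlxipl (-0.34 ± 0.11, fatty acid synthesis), Pfkfb1 (-0.34 ± 0.14, glycolysis), Cyp2d2 (-0.26 ± 0.12, drug metabolism), Cox7a2 (-0.23 ± 0.11, oxidative phosphorylation), Abcb4 (0.35 ± 0.14, bile acids), Rtp4 (-0.47 ± 0.17, interferon response), Postn (0.32 ± 0.18, stellate cells) and Anxa13 (-0.31 ± 0.13, cholangiocytes). Postn and Anxa13 had signals near or below the negative controls in both groups, so these 2 differences do not measure their levels. Tp53inp1 came to 0.21 without TMAO replicate 3, and Pfkfb1 to -0.22 without TMAO replicate 1. Medians for p53 targets (0.08, adjusted p 0.109), autophagy and lysosome (0.05, 0.516), fatty acid and triglyceride synthesis (0.03, 0.874), glycolysis (-0.01, 0.956), drug-metabolising enzymes (-0.03, 0.717) and oxidative phosphorylation (-0.03, 0.516) did not pass. Leaving out 1 array gave p53 medians from 0.06 without TMAO replicate 3 to 0.13 without Control replicate 1. It gave drug-metabolising medians from -0.07 without Control replicate 1 to 0.03 without TMAO replicate 1. Bile acid genes had a median of 5.3e-05 and a mean of -0.0087 (adjusted p 0.984), and interferon response genes a median of -0.01 and a mean of 0.01 (adjusted p 0.728). With 1 array left out, NF-kappaB genes passed without TMAO replicate 1 (adjusted p 0.0492) or Control replicate 3 (0.0453), and p53 and hypoxia genes, both higher, passed without TMAO replicate 2 (0.0394 each). The NF-kappaB median was negative without Control replicate 1 (-0.07) or TMAO replicate 3 (-0.02), and the hypoxia median without Control replicate 3 (-0.03). The fatty acid oxidation median ran from -0.09 without Control replicate 2 to -0.03 without Control replicate 3 or TMAO replicate 3, the autophagy median came to 0.02 without TMAO replicate 1 or Control replicate 3, and the oxidative phosphorylation median to -0.05 without Control replicate 3 and -0.01 without TMAO replicate 3. Signs also turned for NRF2 genes without Control replicate 3 (0.02), for drug-metabolising enzymes without TMAO replicate 1 (0.03) and for fatty acid synthesis without TMAO replicate 1 (-0.0046) or Control replicate 2 (-0.01). The glycolysis median turned positive without TMAO replicate 2, TMAO replicate 3 or Control replicate 3, the interferon median without TMAO replicate 1, TMAO replicate 2 or Control replicate 3, and the bile acid median turned negative without Control replicate 2 or any 1 of the TMAO arrays. The interferon list passed without TMAO replicate 3, with a median of -0.11 and an adjusted p of 0.00874.

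Among the 8139 probe sets with no gene symbol, limma called 0, and 328 had an unadjusted p under 0.05, where 407 were expected by chance. Of the 20 that differed at least 1.5-fold at that p, 13 were higher and 7 lower.

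The PERK-ATF4 and ER chaperone lists rose together with the preset correlation, but did not pass by fry (adjusted p 0.0710 each) and had an adjusted p = 0.215 with an estimated correlation. A trend of the fold change with signal level would raise random lists of like signal, yet both medians lay at percentile 100 of 10000 such lists, whose 99th percentiles were 0.069 and 0.072. TMAO replicate 3 alone is argued against as well, because without it the smaller median was 0.357. The 95% interval of that median, 0.21 to 0.53, came from resampling the list's genes and does not cover the spread between arrays. An effect of TMAO on the cells, which the groups name, stays open as a hypothesis, and no test here went into how it would act. 1 of the 10 splits of the 6 arrays gave as many genes past the adjusted threshold (4, highest other 1), 1 as many past 1.5-fold (99, highest other 72) and 2 as many lists (7, highest other 8), and 10 splits are too few for a share under 0.05.

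Both stress lists were higher on TMAO replicate 3 than on the other TMAO arrays, by 0.39 ± 0.08 and 0.27 ± 0.05 (SE over members). A wider signal range on that array would predict at most 20.6% of either excess. A higher share of hepatocytes on that array stays open. With it go a higher hepatocyte identity list (0.12 ± 0.07) and lower stellate (-0.30 ± 0.05), cholangiocyte (-0.33 ± 0.11) and macrophage (-0.13 ± 0.06) markers. Against it goes the PERK-ATF4 list, 0.27 ± 0.11 above the hepatocyte list, while the ER chaperone list was only 0.155 ± 0.085 above it. Endothelial markers had -0.0012 ± 0.06, which was 0.30 ± 0.08 above the stellate markers, so the markers of other cells did not fall together. Only 6 of 17 endothelial and 11 of 22 stellate markers lay at least 1 log2 unit above the negative controls, so these values decide little. A wider signal range would predict 0.05 of the hepatocyte list's 0.12. A stronger response of the TMAO replicate 3 culture was not tested, and its interferon genes were higher too (0.41 ± 0.13). Control replicate 3 shared part of this. Set against the mean of all 6 arrays, interferon genes averaged 0.10 on it, against -0.07 and -0.05 on Control replicates 1 and 2. Cholangiocyte markers averaged -0.09 on it, against 0.07 and -0.03. Stellate markers went the other way, with 0.02 against -0.03 and 0.06.

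The cell cycle list fell with the preset correlation, but did not pass by fry (adjusted p 0.173) and had an adjusted p = 0.215 with an estimated correlation. Dim probe sets near the background would leave the brighter members in place. Yet the 12 at or above the median signal had a median of -0.247 (95% interval -0.45 to -0.13, resampling genes and not arrays). The next comparison took markers and cell cycle genes at least 1 log2 unit above the negative controls. The lower 95% bound of the difference between their medians, again resampling genes, was 0.267 for cholangiocytes (0.0816 without Control replicate 3). This argues against fewer cholangiocytes. For endothelial cells the bound was 0.106 (-0.0728 without Control replicate 1). For stellate cells and macrophages it was 0.0479 and 0.00195 (-0.0872 and -0.148 without Control replicate 3). Fewer macrophages, endothelial or stellate cells therefore cannot be told apart from an effect of TMAO on the hepatocytes, which was not tested separately. For macrophages the values go both ways, since their list was at an adjusted p of 0.963 without Control replicate 2, where the cell cycle median was -0.33, and passed with array weights (0.0369), without TMAO replicate 2 (0.0179) and without Control replicate 3 (0.0246).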
